A study of Mus musculus with 209 samples.

How the data were processed

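RNA sequencing libraries of 209 sorted cell samples of C57BL/6 mice were analysed from their table of counts. Per the labels' protocols, mice received 5 µg of IL1b, IL6 or TNFa in 120 µL of PBS, or PBS alone, intravenously, and each cell type was sorted 2 times, the last time as 1000 cells into lysis buffer, for ultra-low-input RNA sequencing by the Immunological Genome Project's procedure. Groups, times and replicate numbers came from the sample titles and treatment labels, and each column of the table matched a sample. The titles of 158 screen libraries name the spleen while their tissue label names the peritoneal cavity; the titles were followed. The labels do not say whether a mouse gave more than 1 library, nor how long after LPS the cells were sorted.

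The deposited values are raw counts per gene symbol (55011 genes), whole numbers whose totals differ between libraries. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a to mm10 and counted with featureCounts. The version of featureCounts, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Genes with near-identical copies (Serpina3f, the haemoglobin genes and the lymphocyte receptor constant genes among those used here) are therefore uncertain, as are genes that overlap others on either strand. Of the symbols, 52936 occur in the GENCODE vM21 annotation of GRCm38, which gave the positions. Totals ran from 1094567 to 9291121 counts per library, 13889 to 29259 genes had a count, and mitochondrial genes took 0.0251% to 2.46% of the counts. All table entries named a gene, and 3734 genes had no count in any library. Among 251 pairs of libraries of a group, none were identical and counts differed by more than sampling noise in each (chi-square per degree of freedom 3.04 to 76.0), so each library was counted as 1 replicate.

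The design, the alternatives, the gene lists, the marker lists and the rule for named genes were fixed before the data were examined. Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, genes kept by filterByExpr at its defaults, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Every adjusted p of a gene in the text comes from this test unless DESeq2 is named, and every standard error (SE) is the size of the log2 fold change divided by the root of F. In the screen, 1 fit per cell type held all of its libraries with 1 mean per group; 41 comparisons of a cytokine with PBS and the contrasts between cytokines came from these fits. A fit of all 183 screen libraries tested the cell type by treatment terms of each cytokine together, with the dispersion trend taken from 1 gene in 8. The time course had 1 fit per cell type (10 libraries) and 1 over both, the LPS experiment 1 fit of its 6 libraries, and LPS was set against each cytokine in a fit of both experiments, each response against its own controls. CPM values are counts scaled to 1000000 per TMM-scaled library of the fit; log2 CPM carries a prior count of 2. Where all libraries of a group had no count, the fold is a lower bound from a floor of 3 counts per library mean, which covers counting error only.

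The lists (17 of genes and 20 of cell type markers) were written from general knowledge, and no list was chosen on these samples. Members past the threshold were counted over all genes tested and adjusted over the list alone, and camera (limma 3.58.1, preset correlation 0.01) compared each list with the other genes, with Benjamini-Hochberg adjustment over the lists and cell types of a cytokine or over the lists and times of an experiment. Of 408 list calls among 820 tests, 137 held with an estimated correlation. Named genes were the injected cytokines and their receptors; the 12 genes called in the same direction in the most cell types per cytokine; per cell type the 2 raised most and the 1 lowered most among called genes with a mean of at least 20 CPM in the higher group and no overlap between the groups; in the time course the 4 raised and 2 lowered most; with LPS the 10 raised and 5 lowered most; up to 4 members per list with the smallest adjusted p; and the 6 genes with the smallest adjusted p for dependence on cell type. The text names a part of these, in that order, and a gene that is withheld is not reported here.

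Fold changes of 2 cytokines were correlated across genes beside 20 simulations of unchanged groups against the same PBS libraries, the overlap of independent lists, and PBS libraries split between the cytokines. Receptor levels and numbers of changed genes were related over cell types with Pearson's r and Spearman's rho and two-sided permutation tests of 100000 resamples (scipy 1.17.1, numpy 2.4.6), adjusted over the 6 relations. Markers were averaged as log2 CPM per library. The procedure was tested on simulated counts drawn from the means, dispersions and library sizes of the real groups. In the simulation of TNFa against PBS in MFpc (11671 genes), 64 of 100 genes changed 2-fold and 90 of 100 changed 4-fold were called, and in that of TNFa against PBS in MFrp (12278 genes) 14 and 56. The numbers were lower at 2-fold for LPS (7 and 59), for the difference between Mo.6C+ and MFpc at 8 h (8 and 47), and in the cell type by treatment test of TNFa (1 and 18). Of all calls, 1.74% to 12.7% were of unchanged genes, most at the 8 h difference, with 10% at 24 h in Mo.6C+ and 8.33% for LPS. Camera gave a p under 0.05 for 7 of 200 random lists in simulated TNFa against PBS libraries of MFpc (11681 genes). The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, the replicate number as a block, each library left out in turn, camera with an estimated correlation, genes of at least 20 CPM only for the correlations, and other measures of response for the receptor relations. Figures were drawn with matplotlib 3.10.9 and tables joined with the data.table package (1.17.8) and pandas 2.3.3 (Python 3.11.15).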

Results

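RNA was counted in 209 libraries, each made from about 1000 sorted immune cells of C57BL/6 mice, to find which genes IL1b, IL6 and TNFa change in each cell type. These 3 cytokines are inflammatory mediators, and each was injected intravenously at 5 µg in 120 µL of PBS. In the first experiment, called the screen here, 183 libraries came from 14 cell types sorted 2 h after IL1b, IL6, TNFa or PBS. By the Immunological Genome Project's names, the types were peritoneal macrophages (MFpc) and mast cells (MC), and from the spleen red pulp macrophages (MFrp), Ly6C+ monocytes (Mo.6C+), neutrophils (GN), CD8+ dendritic cells (DC.8+), plasmacytoid dendritic cells (pDC), NK cells (NK), gamma-delta T cells (Tgd), regulatory T cells (Treg), CD4 T cells (T.4), CD8 T cells (T.8), marginal zone B cells (MZB) and follicular B cells (B.fo). PBS groups held 4 or 5 libraries and cytokine groups 3, except that IL1b in MC and DC.8+, IL6 in MC, NK and B.fo and TNFa in T.8 held 2, and pDC had no IL1b libraries. The second experiment followed TNFa at 2, 4, 8 and 24 h against PBS at 24 h in Mo.6C+ and MFpc, with 2 libraries per group. The third compared 3 Mo.6C+ libraries of mice given 1 ng of LPS, a bacterial cell-wall component that acts through TLR4, with 3 controls; the labels give no time for it. Library totals ran from 1094567 to 9291121 counts, and the median was lowest in MC. Depth went with treatment in B.fo, at 6872067 to 8014028 counts with TNFa and 6553203 to 9291121 with IL6 against 2555640 to 4485774 with PBS and 3050467 to 4656127 with IL1b. By smaller gaps, totals also lay apart from those with PBS for IL1b in MFpc and GN, IL6 in DC.8+, GN and T.4 and TNFa in T.8.

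Each cell type carried its own markers. In 13 of the 14 types, every library stood above every library of the other types in the mean log2 CPM of its own marker list; the exception was the B cell list, which was as high in MZB as in B.fo. Neutrophil markers averaged 12.18 ± 0.54 in GN with PBS, mast cell markers 13.11 ± 0.02 in MC and monocyte markers 8.93 ± 0.30 in Mo.6C+ (SD; n = 5, 4 and 5). Some libraries also carried RNA of other cells. In MFrp, haemoglobin transcripts stood at 22165, 43383 and 23010.5 CPM in PBS libraries 1, 2 and 3, against 688 to 8394 in the others. In DC.8+, erythroid markers averaged 4.32 in PBS library 4 and 5.67 in IL1b library 2, and NK markers 5.50 in PBS library 5, 6.25 in IL6 library 3 and 5.26 in TNFa library 2 (log2 CPM). NK markers in DC.8+ averaged 3.35 ± 1.47 with PBS, 1.05 ± 0.04 with IL1b and 4.26 ± 1.25 with TNFa (SD; n = 4, 2 and 3). In MFrp groups they averaged 5.45 to 6.06. Counts without some such libraries, given where they moved by over 1.5 times, were chosen after the data were seen. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between them, which may be technical.

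The receptors of the injected cytokines differed widely between cell types before treatment. With CPM scaled over all PBS libraries, Tnfrsf1a, the main TNF receptor, averaged 1359 ± 171 CPM in GN, 434 ± 58.7 in Mo.6C+, 265 ± 26.3 in MFpc and 160.2 ± 44.8 in MFrp, and 0.256 ± 0.468 in B.fo, 0.0628 ± 0.126 in MZB and 0 in all 4 MC libraries. Il6ra was highest in GN (399 ± 62.1 CPM), Mo.6C+ (364 ± 24.5) and T.4 (219 ± 26.8), and lowest in NK (0.263 ± 0.327). Its partner Il6st averaged 0.961 ± 1.40 CPM in GN. Il1r1, the signalling IL1 receptor, was highest in Tgd (15.7 ± 10.1 CPM) and MFrp (6.84 ± 2.93), and averaged 0.226 ± 0.506 in Mo.6C+ and 0.0427 ± 0.0954 in T.4 (SD; n = 4 or 5).

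At 2 h, IL1b raised some genes in nearly every cell type. Bcl3, an NF-kB cofactor, rose in 13 of 13 cell types, and Socs3, the inhibitor of STAT3 signalling, in 12 of 13, with log2 fold changes of 1.14 to 3.75 and 0.56 to 6.66 over the types that tested them. Fkbp5, Arid5a, Apobec3 and Stat3 also rose in 12 of 13 types, Socs1, Plscr1, Pim1, Nfkbia and Sbno2 in 11, and the early activation marker Cd69 in 11 of 12. In B.fo, Socs3 went from 7.22 ± 4.85 CPM with PBS to 570.4 ± 134 with IL1b (SD, n = 5 and 3; log2 fold change 6.39 ± 0.35, SE; adjusted p = 1.2e-09). The genes that moved most in each type, named from here on, had every cytokine library beyond every PBS library.

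The macrophages, monocytes and neutrophils showed the most changed genes with IL1b. At an adjusted p under 0.05 there were 4656 genes in Mo.6C+ (2437 raised and 2219 lowered), 4509 in MFpc (2498 raised and 2011 lowered), 2504 in GN (1447 raised and 1057 lowered) and 1433 in MFrp (876 raised and 557 lowered). In MFpc, Mt2, a metallothionein that binds zinc, rose by 8.11 ± 0.26 and the monocyte chemokine Ccl7 by 7.59 ± 0.55, while Sox7 fell by 6.44 ± 0.50. Follicular B cell markers averaged 2.85 ± 0.41 log2 CPM in MFpc with PBS and 4.18 ± 0.16 with IL1b, and monocyte markers 4.09 ± 0.22 and 4.77 ± 0.26 (SD, n = 5 and 3). In Mo.6C+, Ch25h, which makes 25-hydroxycholesterol, and Ccl7 had no count in any PBS library and were at least 157-fold and at least 83.9-fold higher, at 72.4 ± 23.7 and 38.7 ± 30.5 CPM; Lpar5 fell by 6.45 ± 0.46. In GN, the neutrophil chemokine Cxcl3 rose by 10.44 ± 0.68 and the lipase Lipg by 8.65 ± 0.67, and the stress factor Atf3 fell by 8.38 ± 0.68. In MFrp, Il12b rose by 9.50 ± 1.23 and Eno2 by 7.35 ± 0.55. The red pulp macrophage markers averaged 10.30 ± 0.35 in MFrp with IL1b and 11.41 ± 0.34 with PBS, and monocyte markers 4.84 ± 0.51 and 3.49 ± 0.68. The count fell to 909 without IL1b 1 in MFrp (IL1b 1 is IL1b library 1). Neutrophil markers in GN went from 12.18 ± 0.54 to 13.25 ± 0.05 (log2 CPM, SD, n = 5 and 3).

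In the lymphocytes, mast cells and DC.8+ fewer genes passed the test. There were 737 in T.4, 673 in DC.8+, 491 in MZB, 459 in NK, 424 in Treg, 292 in Tgd, 232 in MC, 149 in B.fo and 81 in T.8. In Tgd, the cytokine gene Il17f went from 0.179 ± 0.302 to 49.9 ± 29.2 CPM (log2 8.00 ± 1.14; adjusted p = 4.5e-04), Fcgr2b rose by 6.06 ± 0.96 and Il17re, an IL17 receptor chain, fell by 6.46 ± 0.54. NK raised the activation marker Cd83 (4.60 ± 0.61) and Serpina3f (3.87 ± 0.25), Treg Fosl2 (3.85 ± 0.52) and Serpinb1a (3.71 ± 0.67), and T.4 Gadd45g (5.63 ± 0.35) and Frmd4b (5.04 ± 0.40), while Id3 fell by 2.80 ± 0.20 in T.4. Socs3 was the gene raised most or next to most in T.8 (3.49 ± 0.28), MZB (4.63 ± 0.20), B.fo and MC (6.66 ± 0.61), beside Gadd45g in T.8 (3.96 ± 0.27), Zfp36l2 in MZB (3.73 ± 0.25), the prostaglandin receptor Ptger4 in B.fo (2.93 ± 0.32) and the kinase Pim1 in MC (3.95 ± 0.58). CD4 T cell markers averaged 3.00 ± 0.60 in Tgd with PBS and 0.92 ± 0.86 with IL1b (log2 CPM, SD, n = 5 and 3). In DC.8+, Tdgf1 had no count with PBS and was at least 57.0-fold higher, and Itga2b, a platelet gene, rose by 8.36 ± 0.81; without PBS library 4 and IL1b library 2, which carried erythroid markers, the count from 1 IL1b library was 213. B cell markers averaged 3.34 in NK IL1b library 1 and 4.80 in Tgd IL1b library 1 (log2 CPM), against 0.41 and 0.55 and 2.07 and 1.60 in the others. The count moved by over 1.5 times in some types with 1 library left out. In DC.8+ it was 302 without IL1b 2 and 442 without IL1b 3. In MZB it was 745 without IL1b 1, 224 without IL1b 2 and 236 without IL1b 3. In NK it was 259 without IL1b 1. In Treg it was 267 without IL1b 2 and 223 without IL1b 3. In Tgd it was 146 without IL1b 2 and 153 without IL1b 3. In MC it was 111 without IL1b 1 and 73 without IL1b 3. In B.fo it was 77 without IL1b 2 and 71 without IL1b 3. In T.8 it was 38 without PBS 1, 38 without PBS 2, 48 without PBS 3, 41 without PBS 4, 51 without IL1b 1, 50 without IL1b 2 and 29 without IL1b 3.

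Gene groups fixed by pathway before the data were examined held many members that rose with IL1b. Of the NF-kB targets and feedback genes, the members raised numbered 21 of 25 in MFpc, 22 of 26 in MFrp, 15 of 23 in NK, 15 of 25 in GN and 14 of 25 in Mo.6C+ (21, 22, 17, 17 and 14 adjusted over the list alone), and Nfkbia rose in 11 of 13 types. Camera, a set test against the other genes, gave these an adjusted p from 4.6e-19 to 4.9e-04, and from 0.00496 to 0.0254 with an estimated correlation in all but Mo.6C+ (adjusted p = 0.470 with an estimated correlation). In MZB, 5 of 23 (5 adjusted over the list alone) passed the test upwards and camera gave an adjusted p of 0.119. STAT3 targets rose in some lymphocytes and in mast cells, 16 of 19 in T.4, 13 of 21 in Treg, 10 of 20 in MZB, 10 of 19 in MC and 11 of 20 in T.8 (18, 18, 14, 10 and 16 adjusted over the list alone). The camera p of these was from 1.0e-23 to 9.0e-13 and from 8.6e-05 to 0.00867 with an estimated correlation. Of the chemokine genes, 14 of 17 in Mo.6C+, 11 of 14 in MFpc and 9 of 16 in MFrp (14, 11 and 11 adjusted over the list alone) rose, among them Ccl2 in Mo.6C+ (6.11 ± 0.59). Cytokine genes raised numbered 12 of 14 in MFpc, 11 of 18 in Mo.6C+ and 6 of 16 in MFrp (12, 12 and 8 adjusted over the list alone). Of the interferon-gamma-stimulated genes, 18 of 23 (19 adjusted over the list alone) rose in T.4. Type I interferon-stimulated genes rose too, 13 of 30 (21 adjusted over the list alone) in T.4 and 15 of 27 (15 adjusted over the list alone) in GN (adjusted p = 0.416 with an estimated correlation in GN). All 24 ribosome biogenesis genes rose in MFpc (24 adjusted over the list alone) and 15 of 24 (21 adjusted over the list alone) in MZB. Of the glucocorticoid-responsive genes, 7 of 20 in MC, 7 of 14 in MZB and 8 of 15 in T.4 (10, 7 and 8 adjusted over the list alone) rose. In GN, 12 of 18 (12 adjusted over the list alone) glycolysis genes rose (adjusted p = 0.0544 with an estimated correlation) and 8 of 18 (9 adjusted over the list alone) immediate-early genes fell (adjusted p = 0.337 with an estimated correlation). In Treg, 8 of 17 (10 adjusted over the list alone) cytotoxic and effector genes rose.

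By edgeR, IL6 changed the fewest genes in each of the 14 cell types, and by DESeq2 in each but B.fo (350, against 326 with IL1b). Its most shared genes included those of its own signalling. Stat3, its main transcription factor, and the membrane scaffold gene Flot1 rose in 8 of 14 cell types each, Jak3 in 5 of 14, and Flot2 and Zbp1 in 5. Socs3 rose in 6 of 14 types and fell in 1, and Bcl3 rose in 4 and fell in 1. In T.4, Stat3 went from 463 ± 42.9 to 892 ± 133 CPM (SD, n = 5 and 3; log2 0.95 ± 0.10; adjusted p = 1.1e-05) and Socs3 from 235 ± 39.7 to 631 ± 245. At an adjusted p under 0.05 there were 1852 changed genes in MFpc (1107 raised and 745 lowered), 1065 in GN (586 raised and 479 lowered), 738 in Mo.6C+ and 346 in T.4. There were 64 in Treg, 54 in B.fo, 51 in MFrp, 45 in MC, 27 in MZB, 21 in T.8, 19 in pDC, 15 in DC.8+ and 2 in Tgd (Igfbp4, 1.54 ± 0.19, and Flot1, 0.96 ± 0.15). In NK, edgeR called 0 genes, with 980 at an unadjusted p under 0.05, and DESeq2 35. In most types, leaving out 1 library moved the count by over 1.5 times. In GN it was 532 without IL6 1, 325 without IL6 2 and 652 without IL6 3. In Mo.6C+ it was 485 without PBS 3, 374 without IL6 2 and 301 without IL6 3. In T.4 it was 191 without IL6 2. In Treg it was 32 without IL6 1, 21 without IL6 2 and 16 without IL6 3. In B.fo it was 28 without PBS 1, 33 without PBS 2, 5 without IL6 1 and 1 without IL6 2. In MFrp it was 32 without IL6 1, 18 without IL6 2 and 22 without IL6 3. In MC it was 19 without IL6 3. In MZB it was 12 without PBS 1, 6 without PBS 2, 7 without PBS 3, 17 without PBS 4, 8 without IL6 1, 4 without IL6 2 and 11 without IL6 3. In T.8 it was 0 without PBS 1, 0 without PBS 2, 3 without PBS 3, 0 without PBS 4, 0 without IL6 1 and 0 without IL6 2. In pDC it was 6 without PBS 3, 4 without IL6 2 and 7 without IL6 3. In DC.8+ it was 2 without PBS 2, 2 without IL6 1 and 5 without IL6 2. In NK it was 3 without IL6 1. In Tgd it was 1 without PBS 1, 2, 3 or 4 or IL6 1 or 2. Flot1 in Tgd did not pass without PBS 1, 2, 3 or 4 or IL6 1, 2 or 3 (adjusted p = 0.0761 to 0.269). Without the 3 haemoglobin-rich PBS libraries, the MFrp count was 22, and in DC.8+ it was 9 without PBS library 5 and IL6 library 3 and 5 without PBS library 4 and IL1b library 2.

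In MFpc, Spp1 (osteopontin) rose by 3.76 ± 0.52 and Rab3il1 by 3.59 ± 0.31 with IL6. In Mo.6C+, the acute-phase genes Saa3 and Lrg1 rose by 6.28 ± 0.59 and 4.91 ± 0.69, Saa3 from 1.98 ± 2.38 to 155 ± 131 CPM (SD, n = 5 and 3). T.4 raised Etv6 (3.11 ± 0.33) and Skap2 (2.89 ± 0.29), MZB Slc17a9 (1.40 ± 0.20) and Jak3 (1.39 ± 0.16), and pDC Flot1 (1.38 ± 0.14) and Fkbp5 (1.31 ± 0.15). In MC, Gadd45b rose by 4.68 ± 0.81 and Bcl3 by 3.44 ± 0.50, but neither passed without IL6 library 3 (adjusted p = 0.963 and 0.436), which carried T cell markers at 3.18 log2 CPM against 1.35 in the other. In GN, the mitotic kinase Plk1 rose by 4.87 ± 1.10 and the condensin gene Ncapd2 by 4.61 ± 0.91, though Plk1 did not pass without IL6 library 2 (adjusted p = 0.0675). Monocyte markers averaged 3.19 ± 0.21 log2 CPM there and 2.48 ± 0.42 with PBS (SD, n = 3 and 5). Of the cell-cycle genes, 5 of 18 (18 adjusted over the list alone) rose in GN, with a median log2 fold change of 3.21 (camera adjusted p = 1.5e-10; adjusted p = 0.304 with an estimated correlation). The neutrophil granule genes Ngp and Camp rose there by 3.31 ± 0.72 and 3.41 ± 0.74, from PBS libraries that ranged from 326 to 8592 CPM for Ngp; Ngp also rose with IL1b (2.32 ± 0.70) and TNFa (3.14 ± 0.72). With IL1b, Ngp did not pass without PBS library 2 (adjusted p = 0.0557), IL1b library 2 (0.0787) or IL1b library 3 (0.0647). Of the STAT3 targets, 7 of 19 (9 adjusted over the list alone) rose in T.4, with a camera p of 7.9e-07 and 0.0418 with an estimated correlation, and 8 of 19 (8 adjusted over the list alone) did in MFpc (adjusted p = 0.132 with an estimated correlation). In GN, 7 of 18 (8 adjusted over the list alone) STAT3 targets fell (adjusted p = 0.304 with an estimated correlation). So did 8 of 20 (9 adjusted over the list alone) glucocorticoid-responsive genes (camera p = 3.3e-05 and 0.0374 with an estimated correlation), among them Tsc22d3 and Dusp1 (-1.06 and -1.06). Ribosome biogenesis genes rose in MFpc, 22 of 24 (22 adjusted over the list alone), with a camera p of 5.8e-20 and 0.0374 with an estimated correlation.

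By edgeR, TNFa changed the most genes in each cell type except T.8, which had 2 TNFa libraries, and MZB, where IL1b did. By DESeq2 it also did in T.8 (276, against 258 with IL1b). With 1 library left out and the other cytokine's count from all libraries where that library is not part of it, IL1b gave more than TNFa in MC without TNFa 3 (217 for TNFa), in Tgd without TNFa 3 (273) and in T.4 without TNFa 1, 2 or 3 (554, 578 and 550), and as many in Treg without TNFa 3 (424). TNFa gave more than IL1b in MZB without IL1b 2 or 3 (224 and 236 for IL1b) and in T.8 without IL1b 1, 2 or 3 (51, 50 and 29), or without a PBS library (43 and 38 without PBS 1, 44 and 38 without PBS 2 and 46 and 41 without PBS 4). Bcl3 and the caspase inhibitor Birc3 rose in all 14, Socs3, Cd69, Junb and Stat3 in 13, and Icam1, Nfkbia and Batf in 12, while Mxd4 fell in 13 of 14 and Cpt1a, which carries fatty acids into mitochondria, in 13 of 14. Birc3 log2 fold changes ran from 0.52 to 2.94. There were 6448 changed genes in MFpc (3218 raised and 3230 lowered), 6125 in Mo.6C+ (3051 raised and 3074 lowered) and 4197 in GN (2068 raised and 2129 lowered). The others had fewer, with 2848 in MFrp, 2169 in DC.8+, 2106 in NK, 1783 in pDC, 811 in T.4, 660 in Treg, 481 in B.fo, 465 in Tgd, 423 in MC, 340 in MZB and 67 in T.8. Leaving out 1 library moved some of the counts by over 1.5 times. In pDC it was 1166 without TNFa 2. In Treg it was 424 without TNFa 3. In B.fo it was 227 without TNFa 1, 178 without TNFa 2 and 231 without TNFa 3. In Tgd it was 300 without TNFa 1 and 273 without TNFa 3. In MC it was 243 without TNFa 2 and 217 without TNFa 3. In MZB it was 226 without TNFa 1. In T.8 it was 43 without PBS 1, 44 without PBS 2, 41 without PBS 3 and 34 without TNFa 3. With every library thinned to 1000000 counts, the genes changed in MFpc numbered 4173 with TNFa, 2855 with IL1b and 1074 with IL6, so that Mo.6C+ (4690) stood above MFpc with TNFa, and with IL6 GN had 1030, T.8 1 and Tgd 1. For B.fo it gave 436 with TNFa and 79 with IL6. Without the 3 haemoglobin-rich PBS libraries, the MFrp count was 1795.

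In MFpc, the adhesion gene Flrt3 rose by 11.11 ± 0.36 and Acod1, which makes itaconate, by 10.19 ± 0.50, to a mean of 1420.3 CPM. In Mo.6C+, the neutrophil chemokine Cxcl2 and Flrt3 had no count with PBS and were at least 662-fold and at least 106-fold higher, and thrombomodulin (Thbd) fell by 10.01 ± 0.59. GN raised Saa3 (11.17 ± 0.74) and the kinase Ikbke (10.11 ± 0.46), and MFrp raised Cxcl2 (10.22 ± 0.69). DC.8+ raised the sphingosine kinase Sphk1 (8.57 ± 1.00) and Mt2 (8.40 ± 0.60); their CD8 dendritic cell markers averaged 7.34 ± 0.43 log2 CPM against 8.81 ± 0.43 with PBS (n = 3 and 4). In the lymphocytes and pDC, Cd83 led in NK (6.00 ± 0.62) and Tgd (5.96 ± 0.51), Fosl2 and Tnfrsf8 in Treg (3.87 ± 0.52 and 3.42 ± 0.46), Frmd4b and Gadd45g in T.4 (4.76 ± 0.41 and 4.72 ± 0.35), Serpina3f and Casp4 in pDC (4.40 ± 0.58 and 3.98 ± 0.28) and Gadd45g in T.8 (3.37 ± 0.28). Socs3 led in MC (5.77 ± 0.60), MZB (4.02 ± 0.19) and B.fo (5.31 ± 0.34). The cytokine genes themselves responded. Tnf rose in MFpc (6.98 ± 0.24), Mo.6C+ (5.78 ± 0.45), MFrp, GN, DC.8+, NK and pDC, Il1b in MFpc (7.83 ± 0.58), Mo.6C+ (5.53 ± 0.39), MFrp, GN and DC.8+, and Il6 in MFpc (6.95 ± 0.21), Mo.6C+ and MFrp. The decoy receptor Il1r2 rose in Mo.6C+ (3.17 ± 0.70) and GN (1.65 ± 0.20), and Il6ra fell in MFpc (by 1.96 ± 0.15), Mo.6C+ (by 2.01 ± 0.16) and GN (by 1.17 ± 0.17). Of the 6 measured receptor genes of the injected cytokines, 4 rose and 1 fell in Mo.6C+ (4 and 1 adjusted over the list alone). Camera gave this list an adjusted p of 0.409.

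NF-kB targets rose with TNFa in macrophages, monocytes, neutrophils, dendritic cells, NK and T cells. Members raised numbered 24 of 26 in MFrp, 23 of 25 in MFpc, 23 of 25 in Mo.6C+, 22 of 25 in GN, 22 of 26 in DC.8+, 17 of 24 in pDC, 18 of 23 in NK, 18 of 23 in T.4, 17 of 24 in Treg, 17 of 25 in Tgd and 10 of 26 in T.8 (25, 23, 23, 22, 23, 20, 18, 20, 18, 19 and 19 adjusted over the list alone). The camera p ran from 2.5e-24 to 9.1e-10, and from 0.00202 to 0.0120 with an estimated correlation except in Mo.6C+ (adjusted p = 0.205 with an estimated correlation). In MC, MZB and B.fo the list gave 4 of 21 in MC, 4 of 23 in MZB and 4 of 24 in B.fo (4, 5 and 5 adjusted over the list alone), medians of 0.08, -0.07 and 0.15 and camera p from 0.176 to 0.235. STAT3 targets rose there, 10 of 19 in MC, 8 of 20 in MZB and 5 of 19 in B.fo (13, 12 and 10 adjusted over the list alone), with camera p from 9.4e-13 to 0.00671 and from 0.00202 to 0.0361 with an estimated correlation. Interferon-gamma-stimulated genes rose in MFrp and T.4, 21 of 25 in MFrp and 17 of 23 in T.4 (24 and 22 adjusted over the list alone). Type I interferon-stimulated genes went both ways: 16 of 30 in pDC, 15 of 30 in Tgd and 14 of 30 in T.4 (19, 21 and 19 adjusted over the list alone) rose. Against this, 13 of 30 in Mo.6C+ and 11 of 27 in MFpc (15 and 10 adjusted over the list alone) fell. Camera gave these an adjusted p of 0.134 and 0.128. The adjusted p in pDC was 0.148 with an estimated correlation. Ribosome biogenesis genes rose in MFpc (all 24, and 24 adjusted over the list alone) and, at 21 of 24 (23 adjusted over the list alone), in NK, while 5 of 18 (4 adjusted over the list alone) fell in GN (adjusted p = 0.206 with an estimated correlation). Chemokine genes (14 of 17 in Mo.6C+), cytokine genes (12 of 16 in MFrp), metal handling and acute-phase genes (13 of 15 in Mo.6C+), apoptosis regulators (12 of 18 in DC.8+) and antigen presentation genes (13 of 18 in pDC) rose, with 14, 14, 13, 12 and 15 adjusted over the list alone and camera p from 4.5e-13 to 9.2e-06, or from 0.00268 to 0.0462 with an estimated correlation. Trafficking and adhesion genes moved both ways in Mo.6C+ (10 raised and 5 lowered of 21, with 10 and 5 adjusted over the list alone). Camera gave it an adjusted p of 0.110.

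Many of the genes that changed with IL1b changed the same way with TNFa. In MFpc, 2160 genes rose with both and 1753 fell with both, against 666 and 538 for independent lists; 28 went opposite ways. In Mo.6C+ the numbers were 1982 and 1781, against 591 and 542, and in GN 963 and 679, against 267 and 201. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.85 in MFpc, 0.76 in Mo.6C+ and 0.55 in GN. Unchanged groups simulated against the same PBS libraries gave 0.36, 0.36 and 0.35, and with the PBS libraries split so that each cytokine had its own, r was 0.75, 0.62 and 0.36. The covariances were 1.11, 1.60 and 1.41, against simulated values of 0.0306, 0.0771 and 0.147. IL6 and TNFa correlated at 0.46 in MFpc (0.33 with split PBS groups) and 0.32 in Mo.6C+ (0.19). Unchanged groups gave 0.36 and 0.36, so the r in Mo.6C+ did not exceed that of unchanged groups; the covariances were 0.341 and 0.383, against simulated values of 0.0305 and 0.0771.

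The cytokines were also compared directly within each cell type. In MFpc, Il6 was lower with IL1b than with TNFa (log2 difference -3.63 ± 0.21; adjusted p = 4.3e-10), as were Tnf (-3.51 ± 0.23) and Flrt3 (-3.86 ± 0.24). In Mo.6C+, Cxcl2 was lower with IL1b (-3.28 ± 0.25) and Thbd higher (8.06 ± 0.66). In GN, the mitochondrial superoxide dismutase gene Sod2 (-5.17 ± 0.24), Ikbke (-7.24 ± 0.49) and Nfkbia (-1.71 ± 0.11) were lower with IL1b, and in T.4 Nfkbia was lower with IL6 than with TNFa (-2.47 ± 0.12). Genes that differed between IL1b and TNFa numbered 2419 in GN, 1955 in MFpc, 1733 in Mo.6C+, 568 in DC.8+, 381 in MFrp, 197 in NK, 89 in T.4, 59 in B.fo, 44 in MZB and 13 in Treg. In Tgd there were 5 (Cpt1a, 1.19 ± 0.18, Crtam, -1.12 ± 0.15, Il17re, -5.21 ± 0.56, Mmp25, -3.97 ± 0.55, and Pygl, 4.25 ± 0.70). T.8 had 2 (Nfkb2, -1.30 ± 0.17, and Relb, -1.44 ± 0.18). In MC edgeR called 0, with 490 at an unadjusted p under 0.05; no other tool was run on these differences. Some of these genes did not pass with 1 library left out: Nfkb2 in T.8 without IL1b 1, IL1b 2, IL1b 3, TNFa 1 or TNFa 3 (adjusted p = 0.0630 to 0.172), Relb in T.8 without IL1b 1, IL1b 2, IL1b 3 or TNFa 1 (adjusted p = 0.0786 to 0.172), Cpt1a in Tgd without IL1b 2, TNFa 1 or TNFa 3 (adjusted p = 0.0702 to 0.105), Crtam in Tgd without IL1b 2 (adjusted p = 0.0514), Mmp25 in Tgd without IL1b 2 (adjusted p = 0.0514) and Pygl in Tgd without IL1b 2, IL1b 3, TNFa 1 or TNFa 3 (adjusted p = 0.0574 to 0.101). Crtam and Mmp25 were chosen after their values were seen. IL6 and TNFa differed at 4910 genes in Mo.6C+, 4780 in MFpc and 3635 in GN. Some of these counts moved by over 1.5 times with 1 library left out. In Mo.6C+ it was 1117 without IL1b 3. In DC.8+ it was 210 without IL1b 2 and 337 without IL1b 3. In MFrp it was 210 without IL1b 1, 137 without IL1b 2, 193 without TNFa 2 and 224 without TNFa 3. In NK it was 52 without IL1b 2, 123 without IL1b 3 and 94 without TNFa 3. In T.4 it was 36 without IL1b 2, 55 without IL1b 3, 34 without TNFa 1, 54 without TNFa 2 and 47 without TNFa 3. In B.fo it was 0 without IL1b 2, 10 without IL1b 3, 1 without TNFa 1, 0 without TNFa 2 and 0 without TNFa 3. In MZB it was 82 without IL1b 1, 9 without IL1b 2, 10 without IL1b 3, 0 without TNFa 1 and 3 without TNFa 2. In Treg it was 3 without IL1b 1, 5 without IL1b 2, 0 without IL1b 3, 8 without TNFa 1, 23 without TNFa 2 and 0 without TNFa 3. In Tgd it was 13 without IL1b 1, 1 without IL1b 2, 3 without TNFa 1 and 3 without TNFa 3. In T.8 it was 0 without IL1b 1, 0 without IL1b 2, 0 without IL1b 3 and 1 without TNFa 3.

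In 1 fit of all cell types, the response depended on the cell type for many genes. With TNFa, Sod2 had the largest F of the test and ran from -0.13 in T.8 to 7.34 in GN (F = 207), and Fth1, the ferritin heavy chain gene, ran from -0.50 in MC to 3.52 in Mo.6C+ (F = 117). With IL1b, Sod2 ran from -0.24 in Treg to 2.99 in Mo.6C+ (F = 65.3) and the cytoskeletal gene Tes from -0.57 in T.4 to 4.09 in GN (F = 62.0). With IL6, the mitochondrial gene mt-Nd1 ran from -0.56 in MFrp to 2.59 in GN (F = 16.0) and the antiviral deaminase gene Apobec3 from -0.44 in GN to 1.61 in MFpc (F = 15.4). Mitochondrial genes took 0.0251% to 0.0438% of the counts in GN with PBS and 0.0882% to 0.113% with IL6. The cell type by treatment test passed at 7956 of 21905 genes for TNFa, 5012 for IL1b and 1502 for IL6. Single types tested 10591 to 13964 genes, so a pass can reflect a gene absent from some types. Types with coefficients of variation of 0.169 to 0.465 shared 1 dispersion trend.

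Cell types with more receptor transcript before treatment had more changed genes with IL6 and TNFa. Over cell types, the mean log2 CPM of Il6ra with PBS and the log2 number of genes changed by IL6 correlated at r = 0.788 (14 cell types, permutation p = 3.9e-04, adjusted p = 0.00234; rho = 0.763, permutation p = 0.00225). For TNFa, r was 0.638 with Tnfrsf1a (permutation p = 0.0151, adjusted p = 0.0301; rho = 0.820, permutation p = 6.6e-04) and 0.656 with Tnfrsf1b (permutation p = 0.0113, adjusted p = 0.0301; rho = 0.785, permutation p = 0.00137). Without the 2 types farthest from the median receptor level, r was 0.709, 0.592 and 0.561. For Il1r1 and Il1rap against IL1b (13 types), r was -0.0360 and 0.510 (permutation p = 0.908 and 0.0713, adjusted p = 0.908 and 0.107; rho = -0.0604 and 0.511, permutation p = 0.848 and 0.0773). For Il6st against IL6 (14 types) it was 0.0560 (permutation p = 0.851, adjusted p = 0.908; rho = 0.0945, permutation p = 0.750), 6 relations in all. With the median absolute fold change of the STAT3 targets in place of the number of genes, the relation with Il6ra did not pass (r = 0.207, adjusted permutation p = 0.542).

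**Figure D1:**
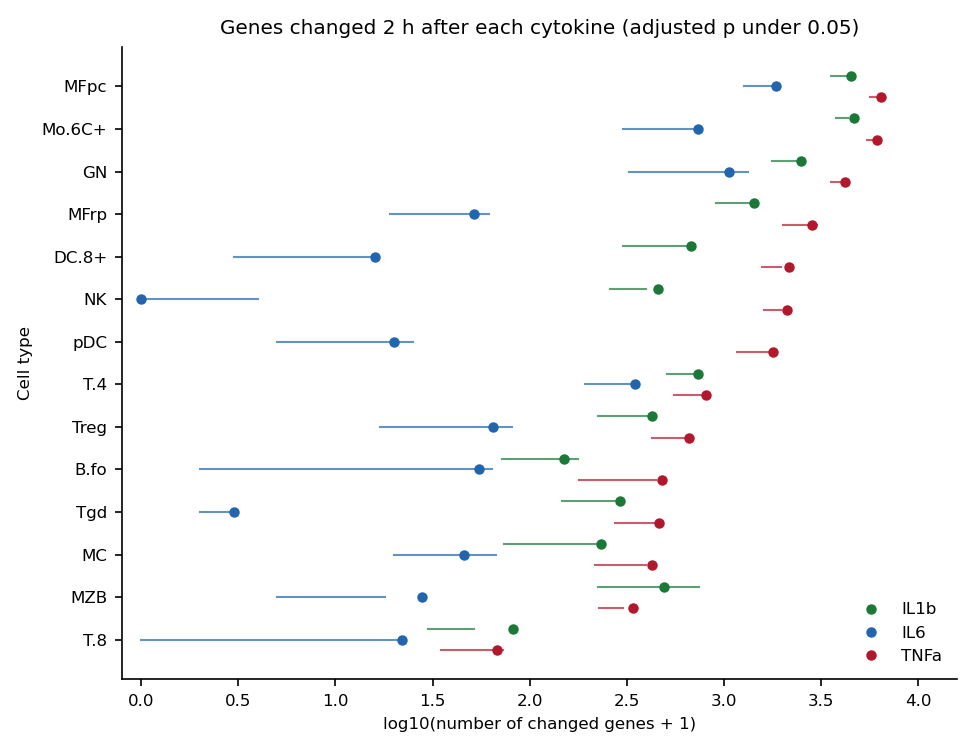
Number of genes changed by each cytokine in each cell type at 2 h (x axis, log10 of the number plus 1; cell types on the y axis), with 1 point per cytokine and lines from the lowest to the highest number with 1 library left out. TNFa changed 6448 genes in MFpc and 67 in T.8, and IL6 1852 in MFpc and 0 in NK.

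**Figure D2:**
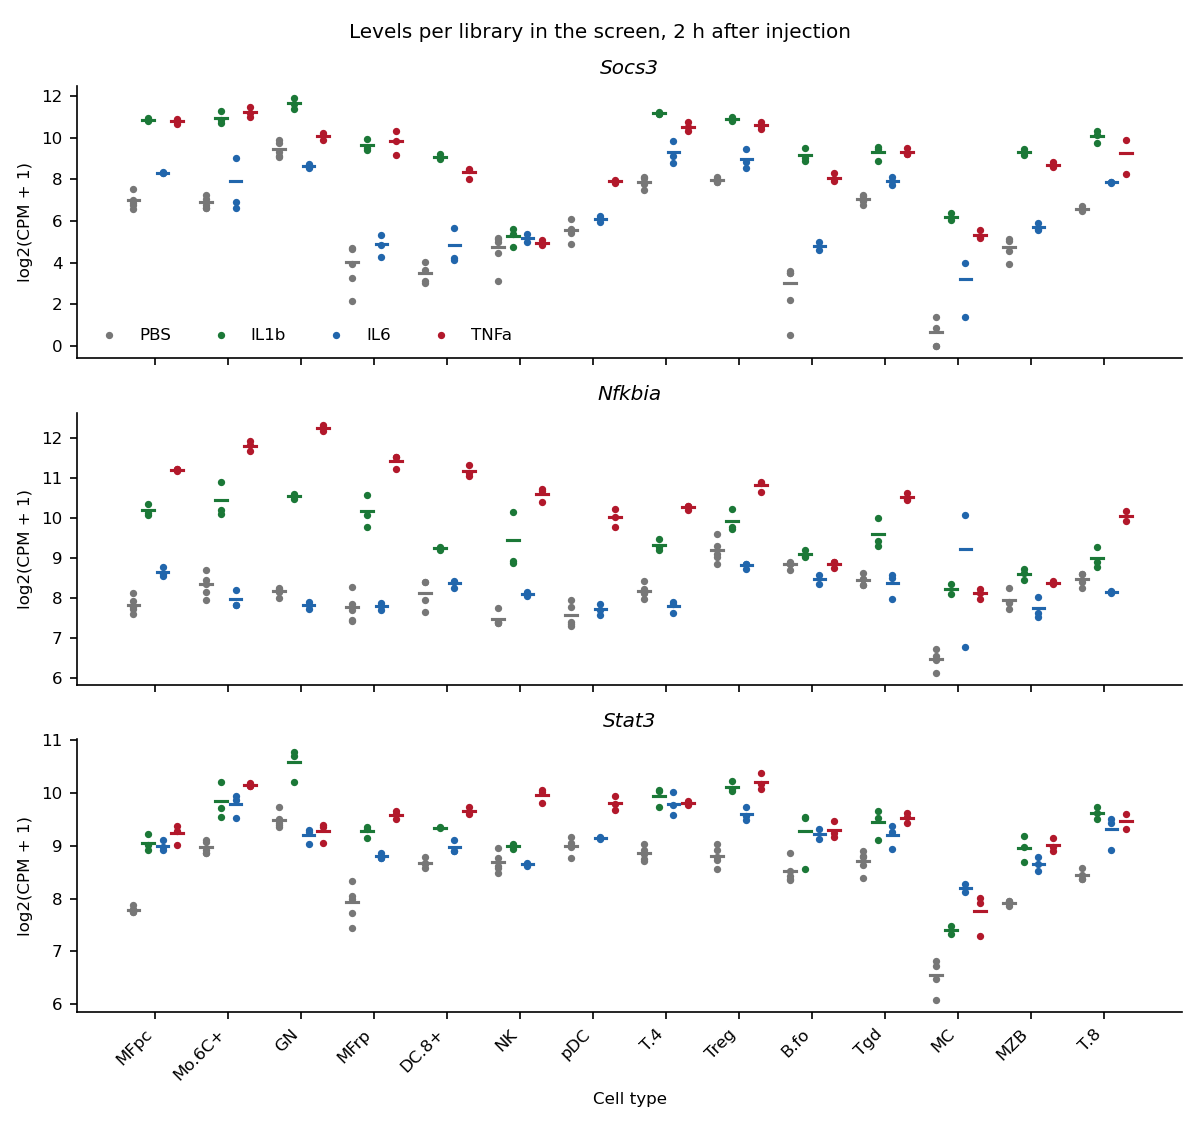
Log2 CPM (plus 1) of Socs3, Nfkbia and Stat3 in every screen library (y axis) by cell type and treatment (x axis), 1 point per library and a bar at each group mean. In B.fo, Socs3 averaged 7.22 CPM with PBS and 570.4 with IL1b.

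In the time course, TNFa changed the fewest genes at 24 h in both Mo.6C+ and MFpc. In Mo.6C+ there were 5098, 4112, 2783 and 564 changed genes at 2, 4, 8 and 24 h, and in MFpc 4474, 4410, 3515 and 825. In Mo.6C+, Saa3 rose by 12.66 ± 0.52 at 2 h and was still raised by 10.72 ± 0.50 at 24 h (0.857 CPM with PBS and 1490.1 at 24 h, n = 2 each). Cxcl2 had no count with PBS and was at least 163-fold higher at 2 h and at least 117-fold higher at 4 h, and the decoy receptor Il1r2 rose by 8.04 ± 0.32 at 8 h. The lectin gene Cd209a fell by 6.56 ± 0.43 at 8 h and 7.29 ± 0.46 at 24 h, and Thbd by 9.14 ± 1.07 at 2 h. In MFpc, the neutrophil chemokine Cxcl3 rose by 10.53 ± 1.53 at 2 h and 11.34 ± 1.51 at 4 h, while Spp1 rose by 6.96 ± 0.62 and the chemokine receptor Ccr2 fell by 7.17 ± 0.76 at 24 h. Camp had no count with PBS in Mo.6C+ and was at least 272-fold higher at 2 h; neutrophil markers averaged 6.34 ± 0.02 log2 CPM in those libraries and 2.12 ± 0.08 with PBS. B cell markers in Mo.6C+ averaged 2.87 ± 0.21 with PBS, 1.29 ± 0.00 at 8 h and 1.48 ± 0.18 at 24 h, and haemoglobin transcripts stood at 20.7 and 94.7 CPM with PBS and 0.509 and 0.965 at 24 h. From PBS, erythroid markers in Mo.6C+ went from 2.62 ± 1.16 to 0.36 ± 0.09 and plasma cell markers from 2.64 ± 0.27 to 4.65 ± 0.24 at 24 h, where neutrophil markers stood at 3.92 ± 0.41, and CD8 dendritic cell markers from 4.10 ± 0.09 to 2.55 ± 0.30 at 4 h. In MFpc, monocyte markers went from 4.25 ± 0.03 to 5.30 ± 0.20 and follicular B cell markers from 3.06 ± 0.34 to 4.08 ± 0.14 at 8 h. Without the 2 h libraries the Mo.6C+ count at 24 h was 864. The only PBS time was 24 h, so at 2, 4 and 8 h the groups compared differed in the time from injection to sorting. Most of these counts moved by over 1.5 times when 1 library was left out. At 2 h in Mo.6C+ it was 3194 without PBS 1 and 3275 without PBS 2. At 4 h in Mo.6C+ it was 2392 without PBS 1, 2427 without PBS 2, 2525 without TNFa 1 and 2654 without TNFa 2. At 8 h in Mo.6C+ it was 1256 without PBS 1, 1359 without PBS 2 and 1773 without TNFa 2. At 24 h in Mo.6C+ it was 151 without PBS 1, 169 without PBS 2, 228 without TNFa 1 and 289 without TNFa 2. At 2 h in MFpc it was 2919 without PBS 1, 2768 without PBS 2, 2704 without TNFa 1 and 2801 without TNFa 2. At 4 h in MFpc it was 2718 without PBS 1, 2671 without PBS 2 and 2451 without TNFa 1. At 8 h in MFpc it was 1805 without PBS 1 and 1768 without PBS 2. At 24 h in MFpc it was 258 without PBS 1, 264 without PBS 2, 461 without TNFa 1 and 1503 without TNFa 2.

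The gene groups were also counted at each time. The chemokine genes raised numbered 13 of 15 at 2 h, 14 of 15 at 4 h, 12 of 15 at 8 h and 3 of 15 at 24 h (13, 14, 12 and 4 adjusted over the list alone) in MFpc. NF-kB targets raised there numbered 24 of 25 at 2 h, 21 of 25 at 4 h, 13 of 25 at 8 h and 3 of 25 at 24 h (24, 21, 14 and 5 adjusted over the list alone). Of the ribosome biogenesis genes, 15 of 24 at 2 h, 18 of 24 at 4 h, 18 of 24 at 8 h and 0 of 24 at 24 h (15, 21, 21 and 0 adjusted over the list alone) rose in Mo.6C+. Glycolysis and hypoxia genes raised numbered 7 of 18 at 2 h, 12 of 18 at 4 h, 17 of 18 at 8 h and 10 of 18 at 24 h (7, 12, 17 and 11 adjusted over the list alone) in MFpc. In Mo.6C+ they numbered 7 of 18 at 2 h, 11 of 18 at 4 h, 15 of 18 at 8 h and 5 of 18 at 24 h (7, 12, 16 and 12 adjusted over the list alone). Among these were the glucose transporter gene Slc2a1 in MFpc (3.92 ± 0.25 at 8 h) and Pfkl in Mo.6C+ (2.33 ± 0.25 at 8 h). Type I interferon-stimulated genes fell in Mo.6C+, 8 of 30 at 2 h, 16 of 30 at 4 h, 25 of 30 at 8 h and 3 of 30 at 24 h (12, 17, 26 and 4 adjusted over the list alone), among them Cmpk2 (by 3.01 ± 0.28 at 8 h) and Irf7 (by 2.38 ± 0.24 at 8 h). Metal handling and acute-phase genes were still raised at 24 h, 8 of 15 in MFpc and 5 of 16 in Mo.6C+ (9 and 8 adjusted over the list alone). Of the cell-cycle genes, 14 of 18 at 2 h, 10 of 18 at 4 h, 16 of 18 at 8 h and 8 of 18 at 24 h (16, 11, 18 and 17 adjusted over the list alone) rose in Mo.6C+. In MFpc, 14 of 18 at 2 h, 10 of 18 at 4 h, 5 of 18 at 8 h and 10 of 18 at 24 h (15, 11, 5 and 13 adjusted over the list alone) fell. With 2 libraries per group, no list that passed camera did so with an estimated correlation: the adjusted p ranged from 0.120 to 0.617 with an estimated correlation. The response differed between Mo.6C+ and MFpc at 1341, 1070, 1256 and 402 of 13914 genes at 2, 4, 8 and 24 h. Saa3 rose more in Mo.6C+ (log2 difference 8.69 ± 0.51 at 2 h and 6.29 ± 0.52 at 24 h), and the cell-cycle genes Mcm5 (4.65 ± 0.52 at 8 h) and Mki67 (4.07 ± 0.41 at 24 h) differed the same way. Some of these counts moved by over 1.5 times with 1 library left out. At 2 h it was 730 without Mo.6C+ PBS 24 h 1, 846 without Mo.6C+ PBS 24 h 2, 2108 without Mo.6C+ TNFa 2 h 2, 746 without MFpc PBS 24 h 1, 743 without MFpc PBS 24 h 2, 715 without MFpc TNFa 2 h 1 and 749 without MFpc TNFa 2 h 2. At 4 h it was 658 without Mo.6C+ PBS 24 h 1, 653 without MFpc PBS 24 h 1, 674 without MFpc PBS 24 h 2 and 668 without MFpc TNFa 4 h 1. At 8 h it was 751 without Mo.6C+ PBS 24 h 1, 775 without Mo.6C+ PBS 24 h 2, 758 without MFpc PBS 24 h 1 and 716 without MFpc PBS 24 h 2. At 24 h it was 208 without Mo.6C+ PBS 24 h 1, 223 without Mo.6C+ PBS 24 h 2, 238 without Mo.6C+ TNFa 24 h 1, 214 without MFpc PBS 24 h 1, 218 without MFpc PBS 24 h 2 and 256 without MFpc TNFa 24 h 1. The TNFa response at 2 h in the screen and in the time course, from separate PBS libraries, correlated across genes at r = 0.79 in Mo.6C+ and 0.85 in MFpc; against 24 h, r was 0.13 and 0.23.

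**Figure D3:**
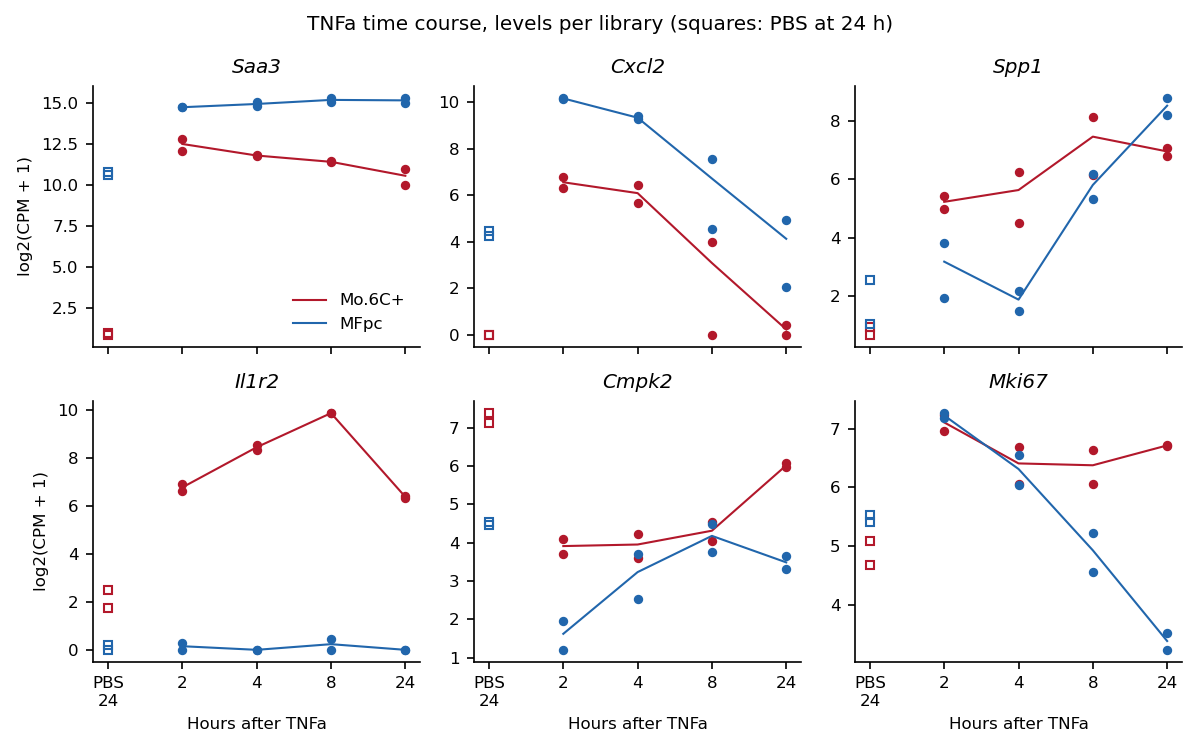
Log2 CPM (plus 1) of Saa3, Cxcl2, Spp1, Il1r2, Cmpk2 and Mki67 (y axes) with PBS at 24 h and with TNFa at 2, 4, 8 and 24 h (x axis, hours) in Mo.6C+ and MFpc, 1 point per library (squares, PBS) and a line through the means; the times are evenly spaced, not to scale. Il1r2 in Mo.6C+ averaged 3.49 CPM with PBS and 934 at 8 h.

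LPS raised interferon-stimulated and chemokine genes in Mo.6C+. The chemokine Cxcl11 had no count in the controls and was at least 183-fold higher. Saa3 rose by 8.32 ± 0.30, the cystine transporter gene Slc7a11 by 7.93 ± 0.78 and Acod1 by 7.61 ± 1.21. Cxcl10 went from 20.2 ± 4.03 to 2242 ± 1682 CPM (SD, n = 3 each; log2 6.79 ± 0.61; adjusted p = 1.8e-04). The lipid receptor gene Lpar5 fell by 5.83 ± 0.65, Irf4 by 5.12 ± 0.77 and Thbd by 4.56 ± 0.56. In all 2055 genes changed (1127 raised and 928 lowered), and by over 1.5 times fewer with some libraries left out, 1113 without control 1, 1278 without control 3, 1099 without LPS 2 and 1252 without LPS 3. Of the type I interferon-stimulated genes 29 of 30 (30 adjusted over the list alone) rose, of the interferon-gamma-stimulated genes 21 of 25 (23 adjusted over the list alone), of the chemokine genes 10 of 13 (12 adjusted over the list alone) and of the metal handling genes 9 of 14 (10 adjusted over the list alone). With an estimated correlation the adjusted p was 0.222, 0.238, 0.222 and 0.222. Plasma cell markers averaged 4.78 and 4.14 log2 CPM in LPS libraries 2 and 3, 2.30 in library 1 and 2.21 to 2.90 in the controls. The LPS response differed from the TNFa response of the screen at 864 of 13006 genes, from the IL1b response at 665 and from the IL6 response at 1290, with no common control and with doses and, as far as the labels say, times that were not matched. Of single genes, Usp18 (log2 difference 4.70 ± 0.34), Mx1 (4.90 ± 0.44) and Ifit1 (5.52 ± 0.54) rose more with LPS than with TNFa, while Per1 (-3.08 ± 0.30) and Dusp1 (-4.66 ± 0.54) rose less or fell more. Some of these counts moved by over 1.5 times with 1 library left out. Against IL1b it was 434 without IL1b 3 and 435 without LPS 3.

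Positions of the genes named most often come from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, counted from 1. All 12 are protein-coding genes, and the span of each runs over its exons and introns. The feedback and transcription factor genes were Socs3 on chromosome 11 from 117966079 to 117970047 (minus strand), Bcl3 on chromosome 7 from 19808462 to 19822770 (minus strand) and Stat3 on chromosome 11 from 100885098 to 100939540 (minus strand). Nfkbia lay on chromosome 12 from 55489410 to 55492647 (minus strand), and Birc3 on chromosome 9 from 7848699 to 7873186 (minus strand). The effector genes were Cxcl2 on chromosome 5 from 90903871 to 90905938 (plus strand), Ngp on chromosome 9 from 110419747 to 110423012 (plus strand), Saa3 on chromosome 7 from 46711998 to 46715700 (minus strand) and Sod2 on chromosome 17 from 13006846 to 13040063 (plus strand). The receptor genes were Il1r2 on chromosome 1 from 40074079 to 40125231 (plus strand), Il6ra on chromosome 3 from 89864059 to 89913196 (minus strand) and Tnfrsf1a on chromosome 6 from 125349362 to 125362484 (plus strand).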

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

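The test of library depth was chosen before its result was seen; all other tests of explanations in this part, and the counts of other splits of the libraries, were chosen after the results were seen.

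In 15 of 116 tests of a group of 4 or 5 libraries (its totals, its own markers, the receptor genes and genes of the text), 1 library stood apart from the others by Dixon's criterion. Chance gives this in about 1 in 20, but not for genes near 0: in 5 of these groups the other libraries had no count of the gene, so that any count in 1 library meets the criterion. The levels of Il1r1, in CPM, were 2.21 in DC.8+ PBS library 4 (others 0), 4.43 in GN PBS library 3 (others 0 to 0.799), 1.13 in Mo.6C+ PBS library 2 (others 0), 0.826 in MZB PBS library 3 (others 0), 1.83 in NK PBS library 4 (others 0 to 0.379) and 0.213 in T.4 PBS library 2 (others 0). Those of Tnfrsf1a were 1.08 in B.fo PBS library 1 (others 0 to 0.203), 0.251 in MZB PBS library 1 (others 0) and 47.8 in pDC PBS library 4 (others 32.4 to 35.2), and of Tnfrsf1b 57.7 in B.fo PBS library 4 (others 31.0 to 37.4). Il6st stood at 3.43 in GN PBS library 4 (others 0 to 0.681), 11.95 in MC PBS library 4 (others 18.8 to 20.2) and 97.8 in Treg PBS library 2 (others 186 to 208), Il17f at 0.698 in Tgd PBS library 5 (others 0 to 0.197) and Saa3 at 6.09 in Mo.6C+ PBS library 1 (others 0.425 to 1.96).

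With the limits above, the response depended on the cell type at 7956 genes for TNFa, 5012 for IL1b and 1502 for IL6. In the time course it differed between Mo.6C+ and MFpc at 1341, 1070, 1256 and 402 genes at 2, 4, 8 and 24 h.

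The number of genes changed by TNFa was 5.18 times as high in GN (4197), the lowest of MFpc, Mo.6C+ and GN, as in T.4 (811), the highest of the T and B cell types. With every library thinned to 1000000 counts this ratio was 4.10, which argues against library depth as the whole cause. A wider spread between replicates would lower the count and leave fold changes alike, but the median absolute log2 fold change of the NF-kB list was higher by 1.5 in the lowest of the 3 types than in the highest of the T and B cell types, which argues against spread as the whole cause. The level of Tnfrsf1a before treatment, which correlated with the number of genes at r = 0.638 over 14 cell types (adjusted permutation p = 0.0301), may contribute, as a hypothesis. Other differences between the cell types were not tested and stay open.

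In Mo.6C+ at 2 h of the time course, the neutrophil granule genes Ngp, Camp and Ltf averaged 303, 152 and 203 CPM, against 0.275, 0 and 0.364 with PBS, although the cells had been sorted 2 times as Ly6C+ monocytes. Against a response of the monocytes to TNFa at 2 h stands the screen, where Ngp reached at most 0.752 CPM in the Mo.6C+ libraries 2 h after TNFa. Against RNA of neutrophils like those of GN with TNFa stand Retnlg, Mmp9 and Cxcr2, abundant there, whose median level was 0.107 of that implied by Ngp, Camp and Ltf, though S100a8 and S100a9 stood at 0.505 and 0.338 of it. RNA of neutrophils like those of GN with IL6, richer in granule transcripts, may be a source and cannot be told apart from others here: the median was 0.214, but Retnlg stood at 0.481 and S100a8 (338 CPM) and S100a9 (230.4 CPM) at 1.26 and 0.839 of the implied level.

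In GN, Ngp rose with each cytokine, to 22718 CPM with TNFa and 27698 with IL6 (25019 above PBS), where the granule gene Camp rose too. Against RNA of another sorted cell type stands Ngp itself, at most 13.6 CPM in the 169 screen libraries of the other types. Neutrophils of an earlier stage in the sorted gate are a candidate. With IL6, the only cytokine weighed here, the cell-cycle list had a median log2 fold change of 3.21. Its list test gave an adjusted p of 0.304 with an estimated correlation. Monocyte markers averaged 3.19 ± 0.21 log2 CPM with IL6 and 2.48 ± 0.42 with PBS. Mitochondrial genes took 0.0882% to 0.113% of the counts with IL6, 0.0502% to 0.0715% with IL1b, 0.0463% to 0.0571% with TNFa and 0.0251% to 0.0438% with PBS, and the reason was not tested. A change of transcription within the same neutrophils was not tested and stays open, and the PBS libraries themselves spanned 326 to 8592 CPM.

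Splits of the same libraries into other groups of the same sizes, the real split counted, were tested where both groups held at least 3 libraries. In 35 comparisons with 35 or 56 splits, at most 1 other split gave as many genes as the real one. Where none did, the real groups gave the highest count of all splits. The other splits put cytokine and PBS libraries into the same group, so their counts are not those of unchanged groups. With 35 or 56 splits and no adjustment over the comparisons, chance is therefore not excluded. The count of IL6 in T.8 fell to at most 3 without PBS 1, 2, 3 or 4 or IL6 1 or 2 and with the replicate block. IL6 in Tgd, MFrp and pDC is taken up below. The real count and the highest of the other splits follow in that order. IL1b against PBS gave 4509 and 1 in MFpc, 459 and 0 in NK, 292 and 18 in Tgd, 424 and 1 in Treg, 1433 and 147 in MFrp, 4656 and 0 in Mo.6C+, 2504 and 102 in GN, 737 and 1 in T.4, 81 and 0 in T.8, 491 and 48 in MZB and 149 and 3 in B.fo. IL6 against PBS gave 1852 and 13 in MFpc, 15 and 1 in DC.8+, 2 and 4 in Tgd, 64 and 2 in Treg, 51 and 390 in MFrp, 738 and 10 in Mo.6C+, 1065 and 179 in GN, 19 and 31 in pDC, 346 and 1 in T.4, 21 and 0 in T.8 and 27 and 2 in MZB. TNFa against PBS gave 6448 and 0 in MFpc, 423 and 70 in MC, 2169 and 250 in DC.8+, 2106 and 0 in NK, 465 and 1 in Tgd, 660 and 2 in Treg, 2848 and 856 in MFrp, 6125 and 1 in Mo.6C+, 4197 and 56 in GN, 1783 and 44 in pDC, 811 and 5 in T.4, 340 and 55 in MZB and 481 and 2 in B.fo. In Tgd, MFrp and pDC with IL6, 1 other of the 56 splits gave more genes than the real one. For MFrp that split set PBS libraries 1, 2 and 3 apart from the others, and its 390 genes point to a structure of these samples, which are those rich in haemoglobin RNA; without them 22 genes changed with IL6. For pDC it grouped PBS libraries 1, 2 and 5, and for Tgd PBS libraries 1 and 4 with IL6 library 2. In the other 33 comparisons, of 3 libraries with 3, the 10 splits are too few for a share under 0.05. IL1b against TNFa gave 1955 and 0 in MFpc, 197 and 0 in NK, 5 and 0 in Tgd, 13 and 0 in Treg, 381 and 0 in MFrp, 1733 and 3 in Mo.6C+, 2419 and 0 in GN, 89 and 0 in T.4, 44 and 0 in MZB and 59 and 0 in B.fo. IL6 against TNFa gave 4780 and 0 in MFpc, 1158 and 0 in DC.8+, 219 and 0 in Tgd, 294 and 0 in Treg, 1695 and 0 in MFrp, 4910 and 0 in Mo.6C+, 3635 and 0 in GN, 672 and 0 in pDC, 354 and 0 in T.4 and 146 and 0 in MZB. IL1b against IL6 gave 2048 and 0 in MFpc, 107 and 2 in Tgd, 188 and 0 in Treg, 821 and 0 in MFrp, 2788 and 0 in Mo.6C+, 1653 and 0 in GN, 250 and 0 in T.4, 15 and 0 in T.8 and 298 and 0 in MZB. LPS gave 2055 and 0. LPS against each cytokine gave 665 and 3 for IL1b, 1290 and 0 for IL6 and 864 and 3 for TNFa.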

How the results depend on the processing

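The counts without libraries that carried RNA of other cells, all alternatives of the contrasts between cytokines, and the leaving out of libraries in tests of differences, were chosen after the data were seen; the other alternatives were chosen before the data were examined. Counts of genes are called moved here where they changed by over 1.5 times, and the cause was not tested unless stated. With RLE factors in place of TMM, 100 of 100 counts did not move, and all 147 named values that were tested again kept their direction and their call, as they did under no filter (147) and DESeq2 (122). The median log2 fold change of all genes lay furthest from 0 with TNFa in GN (-0.21, and -0.21 with RLE factors) and MFrp (-0.14 and -0.14). RLE factors moved the share of raised genes by at most 5.29 percentage points. The median depth was lowest in MC, where 10591 genes had enough counts to be tested, against 13964 in DC.8+.

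DESeq2 gave more genes in each of the 23 counts it moved of 50. IL1b against PBS then gave 1080 in DC.8+, 776 in NK, 528 in Tgd, 258 in T.8, 772 in MZB and 326 in B.fo. IL6 against PBS then gave 89 in MC, 69 in DC.8+, 35 in NK, 10 in Tgd, 236 in Treg, 218 in MFrp, 1216 in Mo.6C+, 57 in pDC, 580 in T.4, 257 in T.8, 157 in MZB and 350 in B.fo. TNFa against PBS then gave 814 in Tgd, 276 in T.8, 575 in MZB and 960 in B.fo. The Mo.6C+ time course then gave 873 at 24 h. With DESeq2 the share of raised genes shifted by over 10 points in some comparisons. IL1b against PBS went from 68.5% to 53.7% in B.fo, 70.1% to 57.3% in DC.8+, 61.1% to 49.7% in MFrp, 64.0% to 53.2% in NK and 81.5% to 70.9% in T.8. IL6 against PBS went from 100% to 82.6% in DC.8+, 82.2% to 69.7% in MC, 100% to 67.9% in MFrp, 85.2% to 66.9% in MZB, 64.4% to 52.1% in Mo.6C+, 90.5% to 68.1% in T.8, 100% to 70.0% in Tgd, 73.4% to 54.7% in Treg and 89.5% to 77.2% in pDC. TNFa against PBS went from 70.2% to 57.6% in T.8.

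Without the filter on low counts, 38 of 100 counts moved, all upwards. IL1b against PBS unfiltered gave 1045 in DC.8+, 493 in Tgd, 405 in T.8 and 259 in B.fo. IL6 against PBS unfiltered gave 118 in MC, 105 in DC.8+, 29 in NK, 33 in Tgd, 142 in Treg, 456 in MFrp, 90 in pDC, 234 in T.8, 111 in MZB and 185 in B.fo. TNFa against PBS unfiltered gave 379 in T.8. IL1b against TNFa unfiltered gave 4 in MC, 1046 in DC.8+, 457 in NK, 113 in Tgd, 104 in Treg, 723 in MFrp, 153 in T.4, 141 in T.8, 148 in MZB and 131 in B.fo. IL6 against TNFa unfiltered gave 126 in MC, 343 in Tgd, 243 in T.8, 220 in MZB and 50 in B.fo. IL1b against IL6 unfiltered gave 65 in MC, 556 in DC.8+, 264 in NK, 284 in Tgd, 186 in T.8 and 154 in B.fo. The Mo.6C+ time course unfiltered gave 957 at 24 h. The difference between Mo.6C+ and MFpc unfiltered gave 669 at 24 h.

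In some comparisons the share of raised genes shifted by over 10 points without the filter. IL1b against PBS went from 81.5% to 67.9% in T.8. IL6 against PBS went from 100% to 81.9% in DC.8+, 100% to 66.7% in Tgd, 100% to 36.8% in MFrp, 64.4% to 53.4% in Mo.6C+, 55.0% to 71.1% in GN, 89.5% to 62.2% in pDC, 90.5% to 72.7% in T.8, 85.2% to 53.1% in MZB and 46.3% to 71.9% in B.fo. TNFa against PBS went from 51.6% to 73.0% in B.fo.

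The replicate numbers do not pair the libraries: same-numbered libraries deviated from their group means together with a median correlation of -0.145 to 0.0348 over 17 fits, 13 of 263 pairs passed 0.1, and 62 of 183 libraries that had a partner of the same number in their fit, over all 3 experiments, lay closest to one of their own number. With the number as a replicate block, 70 of 97 counts did not move, 24 fell and 3 rose. IL1b against PBS with the block gave 120 in MC, 426 in DC.8+, 257 in NK, 141 in Tgd, 251 in Treg and 30 in T.8. IL6 against PBS with the block gave 1 in Tgd, 17 in Treg, 186 in MFrp, 287 in Mo.6C+, 461 in GN, 33 in pDC, 0 in T.8 and 23 in B.fo. TNFa against PBS with the block gave 215 in MC, 1399 in DC.8+, 1362 in NK, 253 in Tgd, 388 in Treg, 25 in T.8 and 248 in B.fo. IL1b against TNFa with the block gave 8 in Tgd, 2 in Treg, 0 in T.8 and 14 in B.fo. IL6 against TNFa with the block gave 15 in T.8. IL1b against IL6 with the block gave 3 in T.8. Of 142 named values, 6 lost their call with the block: Gadd45b (IL6 vs PBS in MC, adjusted p = 0.118), Ncapd2 (IL6 vs PBS in GN, adjusted p = 0.0519), Plk1 (IL6 vs PBS in GN, adjusted p = 0.0995), Flot1 (IL6 vs PBS in Tgd, adjusted p = 0.0813), Nfkb2 (IL1b minus TNFa in T.8, adjusted p = 0.575) and Relb (IL1b minus TNFa in T.8, adjusted p = 0.316). The share of raised genes shifted by over 10 points with the block in some comparisons. IL6 against PBS went from 82.2% to 69.8% in MC, 73.4% to 88.2% in Treg, 100% to 46.2% in MFrp, 89.5% to 75.8% in pDC and 46.3% to 60.9% in B.fo. TNFa against PBS went from 70.2% to 84.0% in T.8. The block was not run for the 3 differences between LPS and a cytokine.

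Leaving out 1 library moved 238 of 650 counts, 229 downwards and 9 upwards, and 13 of 850 named fold changes against a control lost their call. Of 196 values of the 25 named differences between responses, 18 did. Where this left 1 library in a group, that library is assumed to vary like the other groups. It was not run for the fit of all 183 libraries. The ranges of the counts that moved were as follows. IL1b against PBS ran from 73 to 227 in MC, 302 to 634 in DC.8+, 259 to 397 in NK, 146 to 297 in Tgd, 223 to 421 in Treg, 909 to 1481 in MFrp, 29 to 51 in T.8, 224 to 745 in MZB and 71 to 177 in B.fo. IL6 against PBS ran from 19 to 66 in MC, 2 to 14 in DC.8+, 0 to 3 in NK, 1 to 2 in Tgd, 16 to 80 in Treg, 18 to 61 in MFrp, 301 to 756 in Mo.6C+, 325 to 1336 in GN, 4 to 24 in pDC, 191 to 344 in T.4, 0 to 21 in T.8, 4 to 17 in MZB and 1 to 63 in B.fo. TNFa against PBS ran from 217 to 396 in MC, 273 to 483 in Tgd, 424 to 667 in Treg, 1166 to 1786 in pDC, 34 to 72 in T.8, 226 to 301 in MZB and 178 to 447 in B.fo. IL1b against TNFa ran from 210 to 454 in DC.8+, 52 to 222 in NK, 1 to 13 in Tgd, 0 to 23 in Treg, 137 to 305 in MFrp, 1117 to 1962 in Mo.6C+, 34 to 81 in T.4, 0 to 2 in T.8, 0 to 82 in MZB and 0 to 75 in B.fo. IL6 against TNFa ran from 19 to 72 in MC, 459 to 842 in NK, 123 to 167 in Tgd, 183 to 273 in Treg, 1014 to 1635 in MFrp, 381 to 496 in pDC, 215 to 295 in T.4, 7 to 28 in T.8, 84 to 110 in MZB and 9 to 15 in B.fo. IL1b against IL6 ran from 13 to 35 in MC, 70 to 148 in DC.8+, 53 to 126 in NK, 54 to 85 in Tgd, 100 to 138 in Treg, 435 to 674 in MFrp, 145 to 195 in T.4, 1 to 14 in T.8, 164 to 454 in MZB and 13 to 112 in B.fo. The Mo.6C+ time course ran from 3194 to 5383 at 2 h, 2392 to 2654 at 4 h, 1256 to 2005 at 8 h and 151 to 289 at 24 h. The MFpc time course ran from 2704 to 2919 at 2 h, 2451 to 3174 at 4 h, 1768 to 3082 at 8 h and 258 to 1503 at 24 h. The difference between Mo.6C+ and MFpc ran from 715 to 2108 at 2 h, 653 to 784 at 4 h, 716 to 1121 at 8 h and 208 to 402 at 24 h. LPS ran from 1099 to 2351. LPS against each cytokine ran from 434 to 838 for IL1b.

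Without PBS library 4 and IL1b library 2, DC.8+ had 213 genes with IL1b, from a lone library assumed to vary like the other groups, and 5 with IL6, and without PBS library 5 and IL6 library 3 it had 9 with IL6. MFrp without PBS libraries 1, 2 and 3 had 22 with IL6 and 1795 with TNFa, and Mo.6C+ at 24 h without the 2 h libraries had 864. With an estimated correlation, 137 of 408 list calls held, and with RLE factors 406 did. With the median absolute fold change of a list as the response, r was 0.468 for Il1r1 (adjusted permutation p = 0.190), where it had been negative, 0.207 for Il6ra (0.542) and -0.171 for Il6st, which had been positive and was -0.0147 with the number of genes from DESeq2. For Tnfrsf1a and Tnfrsf1b it was 0.895 and 0.850.

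Over genes of at least 20 CPM, all 42 correlations of responses shifted, 39 upwards and 3 downwards. IL1b and IL6 correlated at 0.56 in MFpc, 0.48 in MC, 0.53 in DC.8+, 0.34 in NK, 0.38 in Tgd, 0.46 in Treg, 0.45 in MFrp, 0.53 in Mo.6C+, 0.48 in GN, 0.60 in T.4, 0.58 in T.8, 0.36 in MZB and 0.46 in B.fo. IL1b and TNFa correlated at 0.91 in MFpc, 0.75 in MC, 0.62 in DC.8+, 0.77 in NK, 0.68 in Tgd, 0.70 in Treg, 0.81 in MFrp, 0.84 in Mo.6C+, 0.66 in GN, 0.77 in T.4, 0.61 in T.8, 0.66 in MZB and 0.63 in B.fo. IL6 and TNFa correlated at 0.44 in MFpc, 0.52 in MC, 0.53 in DC.8+, 0.34 in NK, 0.37 in Tgd, 0.40 in Treg, 0.51 in MFrp, 0.36 in Mo.6C+, 0.41 in GN, 0.46 in pDC, 0.53 in T.4, 0.49 in T.8, 0.51 in MZB and 0.66 in B.fo. The screen and the time course at 2 h correlated at 0.90 in Mo.6C+ and 0.93 in MFpc. Responses to 2 cytokines share PBS libraries, and unchanged groups were simulated over all genes only, where they gave r of 0.29 to 0.43, so the values of this paragraph alone do not show agreement of 2 cytokines.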

Other observations

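All tests of explanations in this part were chosen after the results were seen.

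Glucocorticoid-responsive genes rose with TNFa in cell types that held hardly any transcript of 1 of the 2 TNF receptors, Tnfrsf1a (0, 0.0628 and 0.256 CPM in MC, MZB and B.fo). The other, Tnfrsf1b, averaged 23.3, 41.9 and 38.7 CPM there. The members raised numbered 9 of 20 in MC, 6 of 14 in MZB and 7 of 17 in B.fo (11, 7 and 8 adjusted over the list alone), with medians of 1.05, 0.74 and 0.99 and a camera p from 3.0e-09 to 1.3e-05 (adjusted p from 0.00268 to 0.00626 with an estimated correlation). Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, rose by 1.64 ± 0.17 in MC, 2.75 ± 0.20 in MZB and 2.28 ± 0.27 in B.fo. In the same types IL1b raised 7 of 20 in MC, 7 of 14 in MZB and 5 of 17 in B.fo (10, 7 and 9 adjusted over the list alone). In Mo.6C+ with TNFa, 11 of 23 (12 adjusted over the list alone) rose and 6 of 23 (6 adjusted over the list alone) fell, among them Dusp1, raised by 6.58 ± 0.35, and Tsc22d3, lowered (log2 -1.92).

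More cell-cycle genes passed in the time course than in the screen, though both sampled Mo.6C+ and MFpc 2 h after TNFa. In Mo.6C+, 14 of 18 rose in the time course with a median of 1.60, while in the screen 0 rose and 2 fell with a median of -0.85 (edgeR). In MFpc, 14 fell and 1 rose in the time course (median -3.03), and 3 fell and 2 rose in the screen (median -0.02). Adjusted over the list alone, 16 rose in Mo.6C+ and 15 fell in MFpc in the time course, and in the screen 1 fell in each. In the time course the list's adjusted p was 0.583 in Mo.6C+ and 0.327 in MFpc with an estimated correlation. PBS libraries were sorted at 24 h in the time course and 2 h in the screen. In Mo.6C+, Ngp averaged 303 CPM at 2 h of the time course, against at most 0.752 in the screen. Neither was tested as a cause. At 4 and 8 h there, Ngp stood at 0.116 and 0.0790 CPM and S100a8 at 86.9 and 171.

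IL1b changed 4656 genes in Mo.6C+, whose PBS libraries averaged 0.226 CPM of Il1r1. A hypothesis was that IL6 made by other cells after IL1b carries this response, so that few of these genes would differ between IL1b and IL6. Of these genes, 51.7% did, and 40.5% to 53.7% with 1 library left out, so the response was not that to injected IL6 alone. Another was that TNFa carries it, and 20.5% differed between IL1b and TNFa (15.2% to 24.2% with 1 library left out). In Tgd, where Il1r1 was highest (15.7 CPM), the shares for IL6 and TNFa were 31.5% and 1.03%, and in MC (2.61 CPM) 10.3% and 0%. The genes were also chosen with the same IL1b libraries, so these shares alone do not tell a carried from a direct response. Whether a released cytokine carries the response in Mo.6C+ stays open, as does a direct action through few receptors. Released cytokine may also differ from the injected one in amount and time, which was not tested and limits both comparisons.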
